A study of Mus musculus with 6 samples.

How the data were processed

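RNA sequencing was performed on hematopoietic stem cells sorted from adult C57BL/6 mouse bone marrow. The sort kept cells that lack lineage markers and carry Sca-1, c-Kit and CD150 but not CD48. Per the labels' protocols, about 500 cells were sorted for each library and libraries were made by Smart-seq2, a full-length cDNA method that amplifies polyadenylated RNA by PCR, keeps no strand and carries no molecular identifiers. There were 6 libraries, 3 from control mice (floxed Rbfox2 without Cre) and 3 from mice in which floxed Rbfox2 was combined with Vav1-Cre, which recombines in blood cells. The exon removed by the deletion is not given in the sources used here.

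The values used were counts of reads per gene, deposited by the authors without normalization and keyed by Ensembl gene identifier. Per the submitters' processing notes, the tools were Trimmomatic 0.39, featureCounts and DESeq2 1.36.0, with genome build mm10. The aligner, the annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. For that reason genes with near-identical copies, among them the ribosomal protein genes and Hspa8 with their processed pseudogenes, and genes that overlap others, have uncertain counts. The table held 22969 identifiers, of which 60 stood on more than 1 row. Those 134 rows held 0.449% of the counts and were summed per identifier. Symbols were found for 22831 identifiers, and the other 138 held 0.0131% of the counts. Gene coordinates, transcript lengths and GC content came from a GENCODE annotation of the same build. Length and GC content were those of each gene's longest annotated transcript, which need not be the form expressed. Of the 12350 genes tested, 12328 had a length and a GC value.

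Before any test the libraries were compared pairwise. For genes with more than 20 counts summed over a pair, the chi-square per degree of freedom was 3.44 for controls 1 and 3 and between 156 and 808 for the other pairs. Controls 1 and 3 differed by more than Poisson noise, but 45.4 times less than the closest other pair, and no gene had at least 100 counts in one and at most 1 in the other. Their counts were therefore summed and counted as 1 sample, which left 2 control samples against 3 libraries labelled Rbfox2-deleted. The design fixed before the data were examined had 6 separate samples, and that fit was kept as an alternative. The labels give separate mice, but these p-values measure only the spread between 5 samples.

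Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group with a minimum count of 10 and a minimum total of 15, TMM scaling, glmQLFit and glmQLFTest, two-sided, group as the only term). P values were adjusted by Benjamini-Hochberg over 12350 genes with a threshold of 0.05. CPM (counts scaled to a common library total) of named genes were further scaled by the TMM factors, and log2 fold changes are libraries labelled Rbfox2-deleted minus control. SE was the fold change divided by the square root of the F statistic. Before the data were examined, 47 gene lists were written from textbook knowledge for this cell type and for the subject of the series, protein homeostasis and self-renewal. Of these, 34 pathway lists and 8 lists of other cell types had at least 5 genes tested. These 42 lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists, and again with the correlation estimated from the residuals and with fry. Summed CPM of marker and quality lists were compared by exact two-sided permutation tests, for which 2 samples against 3 allow no p below 0.1.

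Named genes followed a rule fixed before the data were examined. Rbfox2 came first. Since no gene passed the threshold, 5 genes per direction with the smallest p among those whose samples of one group lay all above the other were named, leaving out predicted genes, pseudogenes, mitochondrial genes and receptor segments. For each list past the camera threshold, up to 4 members with the smallest p in the direction of the list were named, and for other lists the member with the smallest p, as a value only. Of the genes this rule chose, 1 is not reported here. The numbers of members past the threshold are given over all genes and adjusted over the list alone.

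The same scripts were tested on simulated counts for the 5 samples of this comparison, drawn from the real means and library sizes. At each of 4 fold sizes 50 genes were changed, picked from those with a mean above 5 CPM. With the dispersions estimated from these libraries, over 12038 genes, 0% of genes changed 2-fold, 2% of those changed 4-fold, 18% changed 8-fold and 32% changed 16-fold were recovered, with 1 false call. With a dispersion of 0.05 for every gene, over 12310 genes, 36% of genes changed 2-fold and 100% of those changed 4-fold were recovered, with 3 false calls. A simulated list set to 0.64 of control had a camera adjusted p of 0.11 under the estimated dispersions and 1.04e-19 under the low one. Its genes were drawn at random from genes of any level, so it does not stand for a list of abundant genes. Of 41 unchanged lists, 0 were called in either. Simulated genes were drawn independently of one another, so these lists could not show false calls that arise from correlation between genes.

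The depth was between 23474895 and 55151484 counts per library, so a count of 3 corresponded to between 0.0544 and 0.128 CPM. Poisson intervals (exact, 95%) cover counting error only, because PCR copies without molecular identifiers are not independent molecules. Alternatives planned before the data were examined were DESeq2 1.42.0, limma-voom, other scaling factors, other count filters, a robust fit, a block on the replicate number, a correction for GC content, other thresholds, leaving out mitochondrial and hemoglobin genes, and leaving out each library. Those added after were 6 separate libraries, leaving out controls 1 and 3, sex of the mice as a covariate, a correction for transcript length, leaving out identifiers on several rows, and the GC correction and removal of mitochondrial and hemoglobin genes in the list tests. No library was left out of the main test. Splicing, the process in which Rbfox2 acts, was not analysed here because gene counts hold no junctions.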

Results

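The series addresses how Rbfox2, an RNA-binding regulator of alternative splicing, acts on self-renewal and protein homeostasis of hematopoietic stem cells. RNA of about 500 sorted stem cells per mouse was sequenced in 3 control and 3 Rbfox2-deleted libraries. Control libraries 1, 2 and 3 held 47895459, 51643037 and 55151484 counts, and 16953, 16675 and 17087 genes were detected in them. Rbfox2-deleted libraries 1, 2 and 3 held 23474895, 35650284 and 33345370 counts, with 14154, 15950 and 15972 genes detected. Depth was lower in every library labelled Rbfox2-deleted than in any control. Mitochondrially encoded genes took 5.52%, 5.58% and 5.53% of the counts in the controls and 3.90%, 5.19% and 4.05% in the libraries labelled Rbfox2-deleted.

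The libraries differed in ways the group labels did not explain. Controls 1 and 3 were nearly identical (Spearman correlation 0.969 across genes, against 0.753 to 0.917 for the other pairs) and were counted as 1 sample, so that n = 2 for control and n = 3 for Rbfox2-deleted throughout. They differed by more than Poisson noise, with a chi-square per degree of freedom of 3.44, while the closest other pair had 156. Rbfox2-deleted 1 stood apart from the other 4 samples on the first principal component, which held 65.0% of the variance, at 318.7 against -72.1 to -88.3. The mice also differed in sex. Xist, the RNA of the inactive X chromosome, had 2821 counts in Rbfox2-deleted 1 and 2467 in Rbfox2-deleted 3, and at most 55 in the other libraries. The Y-linked gene Eif2s3y had 0 counts in those 2 libraries and between 576 and 1560 in the controls and Rbfox2-deleted 2.

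Rbfox2 reads were scarce and went against the labels of 2 libraries. Rbfox2 (ENSMUSG00000033565, mm10 chromosome 15, 77078990 to 77307004, minus strand, protein coding) had 238 counts in control 1, 11 in control 2 and 250 in control 3, or 4.97, 0.213 and 4.53 CPM. In Rbfox2-deleted libraries 1, 2 and 3 it had 2, 87 and 10 counts, or 0.0852, 2.44 and 0.300 CPM. The 95% Poisson interval of Rbfox2-deleted 2 (1.95 to 3.01 CPM) lay above that of control 2 (0.106 to 0.381 CPM). The log2 fold change was -1.49 (SE 2.0, edgeR adjusted p = 0.923), and it lay between -3.76 without Rbfox2-deleted 2 and -0.97 without Rbfox2-deleted 1. It was -0.13 with sex as a covariate and turned to 1.90 without controls 1 and 3. The counts take in exons that a deletion could leave in place, so they do not settle whether the gene was deleted, and every direction given here rests on the labels. Of the related genes, Rbfox1 (ENSMUSG00000008658) had 69 counts in control 2 and at most 3 in any other library, and Rbfox3 (ENSMUSG00000025576) had between 1 and 3 counts in each.

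**Figure D1:**
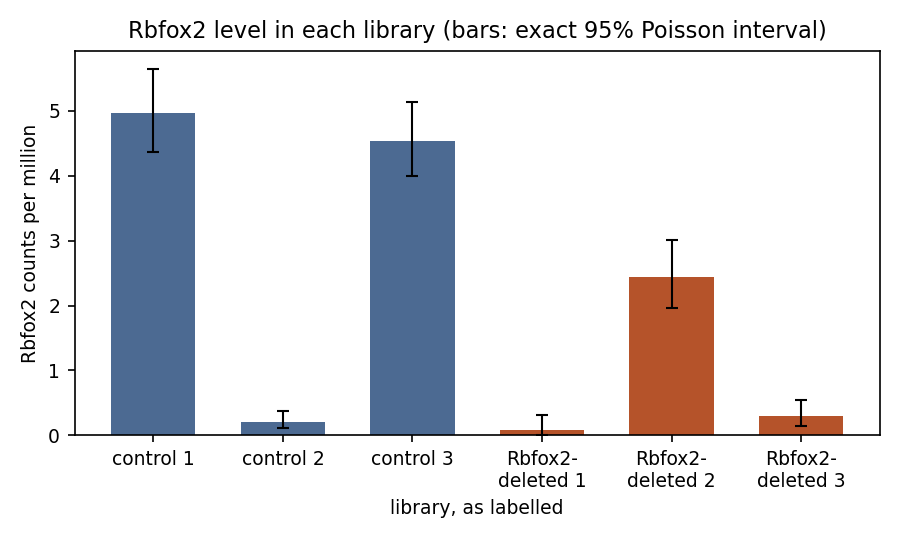
Rbfox2 CPM (y axis, from 0) in each of the 6 libraries (x axis), with exact 95% Poisson intervals that cover counting error only. Control 2, at 0.213, lies near Rbfox2-deleted 1 and 3, at 0.0852 and 0.300, while Rbfox2-deleted 2, at 2.44, lies between them and controls 1 and 3.

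Which genes differ in stem cells labelled Rbfox2-deleted was the main comparison. The genes with the smallest p among those higher were Cct3, a subunit of the TRiC chaperonin that folds actin and tubulin, the succinyl-CoA ligase subunit Sucla2, the Golgi GTPase Arf4, the constitutive Hsp70 chaperone Hspa8, and Nrros, a protein that holds latent TGF-beta. Those lower were the nuclear speckle protein Pnn, the membrane protein Pdzk1ip1, the ribosomal protein Rpl37, the membrane protein Tmem40, and Nop10, a protein of box H/ACA ribonucleoproteins. None of these 10 passed the threshold, each with an edgeR adjusted p = 0.387, although the 5 samples were fully separated for each. DESeq2 called 8 of them, all but Tmem40 and Nop10. Cct3 had 161 ± 16.4 CPM in control (SD, n = 2) and 485 ± 9.78 CPM in libraries labelled Rbfox2-deleted (SD, n = 3), and Hspa8 had 434 ± 25.5 and 1332 ± 235 CPM. Pnn had 290 ± 66.5 and 74.7 ± 17.4 CPM, and Rpl37 had 1350 ± 31.7 and 629 ± 13.7 CPM.

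The log2 fold changes of the higher genes were 1.59 (SE 0.240) for Cct3, 2.27 (SE 0.350) for Sucla2, 1.75 (SE 0.274) for Arf4, 1.62 (SE 0.258) for Hspa8 and 1.87 (SE 0.315) for Nrros. Those of the lower genes were -1.96 (SE 0.336) for Pnn, -1.29 (SE 0.222) for Pdzk1ip1, -1.10 (SE 0.202) for Rpl37, -1.39 (SE 0.268) for Tmem40 and -1.23 (SE 0.237) for Nop10. On mm10, Cct3 (ENSMUSG00000001416) lies on chromosome 3 from 88297116 to 88321767, Sucla2 (ENSMUSG00000022110) on chromosome 14 from 73525319 to 73596142, and Arf4 (ENSMUSG00000021877) on chromosome 14 from 26638074 to 26665084. Hspa8 (ENSMUSG00000015656) lies on chromosome 9 from 40800984 to 40810087 and Nrros (ENSMUSG00000052384) on chromosome 16 from 32142785 to 32165594. Pnn (ENSMUSG00000020994) lies on chromosome 12 from 59066884 to 59073998, Pdzk1ip1 (ENSMUSG00000028716) on chromosome 4 from 115088708 to 115093899, and Rpl37 (ENSMUSG00000041841) on chromosome 15 from 5116645 to 5119140. Tmem40 (ENSMUSG00000059900) lies on chromosome 6 from 115729131 to 115762410 and Nop10 (ENSMUSG00000027133) on chromosome 2 from 112261926 to 112263269. All 10 are protein coding, and counts cover their exons. Rpl37 and Hspa8 have processed pseudogenes, which makes their counts uncertain, and Rpl37 stood on more than 1 row of the table.

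**Figure D2:**
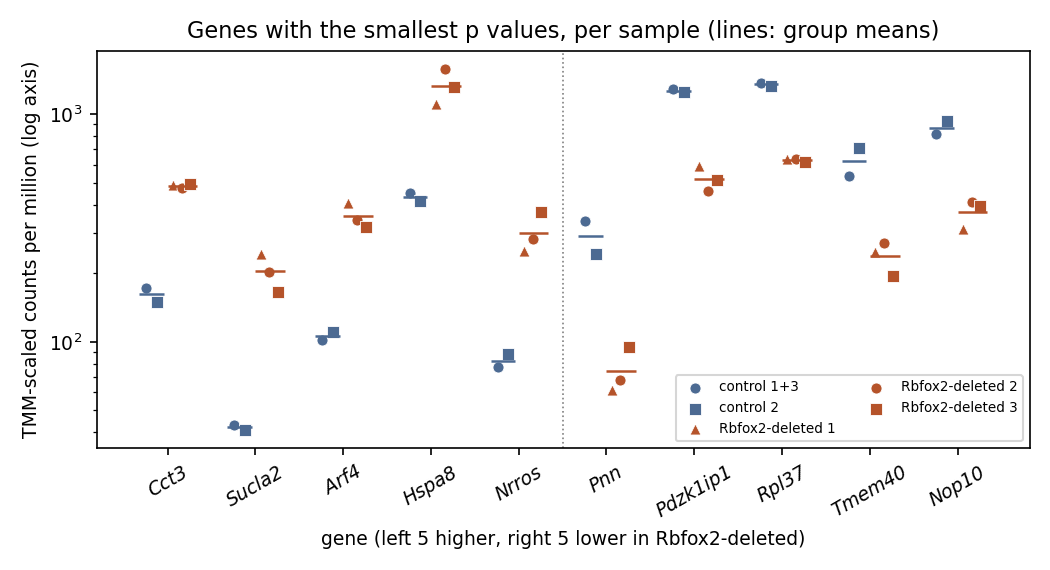
TMM-scaled CPM (log y axis) of the 10 genes with the smallest p values (x axis) in the 2 control samples and the 3 libraries labelled Rbfox2-deleted, with lines at the group means. The samples of the groups do not overlap for any of the 10 genes, which is the rule they were chosen by, and none passed the edgeR threshold (adjusted p = 0.387).

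Over all genes, edgeR's quasi-likelihood test called 0 of 12350, with 658 genes higher and 563 lower at an unadjusted p under 0.05. That is 1221 genes against 617.5 expected by chance on average. The highest count from another split of the same 5 samples was 896. DESeq2 called 477 genes, 236 higher and 241 lower. Of these, 257 (53.9%) had a sample under 10 counts, and 374 had an edgeR unadjusted p under 0.05. Low counts were common among all genes, since Rbfox2-deleted 1 reached 10 counts for 8200 of 22969 identifiers. The limma-voom test called 0, with 756 higher and 930 lower at an unadjusted p under 0.05. The groups did not overlap for 1836 genes that were higher and 2121 that were lower, 32.0% of those tested. Chance gives 20% on average. The common dispersion was 1.09, a biological coefficient of variation of 104%. The split of higher against lower genes moved with the scaling, to 339 and 1087 with upper quartile factors and 469 and 212 with a GC correction. At an unadjusted p under 0.05 edgeR counted 2924 genes without Rbfox2-deleted 1, 2145 with 6 separate libraries, 465 without control 2 and 371 with sex as a covariate, and 0 adjusted in each.

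Genes of cytosolic chaperones and tRNA synthetases were higher as groups in libraries labelled Rbfox2-deleted. Of 50 tested heat shock and cytosolic chaperone genes, 34 had values above control, and the list median was 0.62 on the log2 scale. It was 0.57, 0.51 and 0.52 in libraries 1, 2 and 3. The list rose by camera (adjusted p = 0.00149), and the call was lost at adjusted p = 0.54 with an estimated correlation. No member passed over all genes by edgeR, and 7 were raised adjusted over the list alone. DESeq2 called 4 members higher, Cct3, Cct8, Dnajb6 and Hspa8, and 1 lower, Hspb1. The leading members, with log2 values, were the chaperonin subunits Cct3 (1.59), Cct8 (1.37, SE 0.240) and Cct5 (1.68, SE 0.341) with Hspa8 (1.62). Of 23 cytosolic tRNA synthetase genes, 18 lay above control, with a median of 0.84 (camera adjusted p = 0.00259; adjusted p = 0.54 with an estimated correlation). Gars had 21.0 ± 7.24 CPM in control (SD, n = 2) and 88.5 ± 15.8 CPM in libraries labelled Rbfox2-deleted (SD, n = 3), and Kars had 88.0 ± 3.16 and 246 ± 81.9 CPM, while Hars (log2 1.43, SE 0.422) and Yars (1.95, SE 0.60) followed.

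Autophagy and lysosome genes were higher as a group, with 46 of 65 above control and a median of 0.77 (camera adjusted p = 0.00263; adjusted p = 0.54 with an estimated correlation). Ctsb, a lysosomal cathepsin, had 139 ± 13.3 CPM in control (SD, n = 2) and 399 ± 46.9 CPM in libraries labelled Rbfox2-deleted (SD, n = 3). The autophagy receptor Sqstm1 had 78.0 ± 30.8 and 212 ± 8.77 CPM, and the lysosomal membrane protein Lamp2 had 17.8 ± 1.19 and 74.7 ± 16.3 CPM. Atp6ap1, an accessory subunit of the lysosomal proton pump, had a log2 value of 1.77 (SE 0.435). The list median was 0.13 in Rbfox2-deleted 1, 0.84 in Rbfox2-deleted 2 and 0.61 in Rbfox2-deleted 3. Other proteostasis lists did not pass. The proteasome list had 22 members above and 27 below control (camera adjusted p = 0.870), with Psmb5 at log2 -1.13 (SE 0.258). The unfolded protein response list (adjusted p = 0.302) had the disulfide isomerase Pdia3 at 1.37 (SE 0.268), the ATF4 target list (adjusted p = 0.558) had Nupr1 at -1.88 (SE 0.516), and the ubiquitin and ERAD list (adjusted p = 0.122) had Ube2g2 at 1.58 (SE 0.432). None of these members passed the edgeR test over all genes or adjusted over the list alone.

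**Figure D3:**
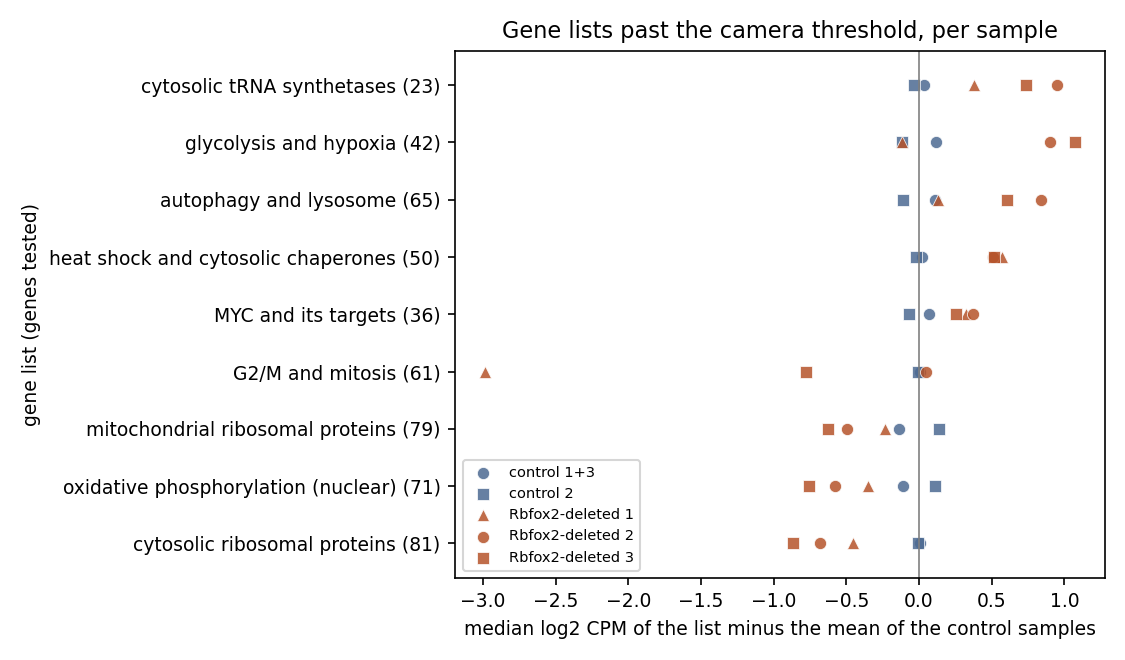
Median log2 CPM of each gene list past the camera threshold, minus the mean of the control samples (x axis), for the 2 control samples and the 3 libraries labelled Rbfox2-deleted; the number of genes tested stands beside each list (y axis). In libraries 1, 2 and 3 labelled Rbfox2-deleted, chaperone genes lie at 0.57, 0.51 and 0.52. Cytosolic ribosomal protein genes lie at -0.45, -0.68 and -0.86, while G2/M genes range from -2.99 to 0.05. With a correction for transcript length the median log2 fold change of the ribosomal list was 0.10, against 0.47 for all genes. Without it these values were -0.64 and 0.11.

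Ribosomal protein and respiratory chain genes were lower as groups. Of 81 cytosolic ribosomal protein genes, 79 lay below control, and the list median was -0.64, or 64.2% of control. The list fell by camera (adjusted p = 6.3e-16; adjusted p = 0.54 with an estimated correlation), and 14 members were lowered adjusted over the list alone, 0 over all genes by edgeR, with 39 lower at an unadjusted p under 0.05. By DESeq2, Rpl37 passed (adjusted p = 0.0488). Rps20 had 1015 ± 63.7 CPM in control (SD, n = 2) and 472 ± 64.9 CPM in libraries labelled Rbfox2-deleted (SD, n = 3), and Rps9 had 1559 ± 46.2 and 790 ± 69.1 CPM. Of 71 nuclear genes of oxidative phosphorylation, 60 lay below control, with a median of -0.57 (camera adjusted p = 2.22e-06; adjusted p = 0.54 with an estimated correlation). The complex I subunits Ndufs7 (log2 -1.16, SE 0.249) and Ndufb9 (-1.12, SE 0.283), the cytochrome oxidase subunit Cox6c (-1.11, SE 0.269) and the ATP synthase subunit Atp5g3 (-1.03, SE 0.253) led this list. Of 79 mitochondrial ribosomal protein genes, 59 lay below control, with a median of -0.44 (camera adjusted p = 0.00263; adjusted p = 0.54 with an estimated correlation), led by Mrpl46 (-1.39, SE 0.361), Mrps21 (-1.17, SE 0.322), Mrpl18 (-0.97, SE 0.280) and Mrpl30 (-0.85, SE 0.251). DESeq2 called 1 member of this list, Mrps27, as higher. These are short transcripts, with list median lengths of 1094, 1232 and 1962 bases. With a correction for transcript length the list medians were 0.10 for cytosolic ribosomal proteins, 0.23 for oxidative phosphorylation and 0.19 for mitochondrial ribosomal proteins. The median of all genes was then 0.47 (camera adjusted p = 0.772, 0.725 and 0.901). With a GC correction, oxidative phosphorylation and mitochondrial ribosomal medians relative to all genes were -0.55 and -0.39. In the main fit these were -0.68 and -0.56, so most of the size remained. The mitochondrial ribosomal call was also lost without control 2 (adjusted p = 0.244) and without Rbfox2-deleted 3 (adjusted p = 0.164), and it and the oxidative phosphorylation call were lost with a GC correction (adjusted p = 0.492 and 0.316).

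Glycolysis and MYC target genes were higher, and G2/M genes lower, as groups. Of 42 glycolysis and hypoxia genes, 32 lay above control, with a median of 0.80 (camera adjusted p = 0.0141; adjusted p = 0.54 with an estimated correlation). The glycolytic enzymes Pgam1 (log2 1.42, SE 0.304), Pkm (1.51, SE 0.449) and Pgk1 (1.77, SE 0.528) and the pyruvate dehydrogenase kinase Pdk3 (1.54, SE 0.407) led the list. Its medians were -0.11, 0.90 and 1.07 in Rbfox2-deleted libraries 1, 2 and 3. The camera call was lost without Rbfox2-deleted 2 (adjusted p = 0.0874) and without Rbfox2-deleted 3 (adjusted p = 0.0640). It was also lost with a transcript length correction (adjusted p = 0.0669) and with a replicate block and GC correction together (adjusted p = 0.0520). The length-corrected median was 0.99, or 0.52 relative to all genes, against 0.69 relative to all genes in the main fit. Of 36 genes in the list of MYC and its targets, 25 lay above control, with a median of 0.52 (camera adjusted p = 0.0225; adjusted p = 0.54 with an estimated correlation). It was led by the co-chaperone Fkbp4 (1.24, SE 0.297), the arginine methyltransferase Prmt5 (1.62, SE 0.445), the cap-binding factor Eif4e (1.21, SE 0.341) and Mycn (1.68, SE 0.537), and its call was lost without Rbfox2-deleted 2 (adjusted p = 0.0567), without Rbfox2-deleted 3 (adjusted p = 0.0542), without controls 1 and 3 (adjusted p = 0.0962), after a stricter filter (adjusted p = 0.189) and with sex as a covariate (adjusted p = 0.0801). Of 61 G2/M and mitosis genes, 37 lay below control, with a median of -0.21. Without Rbfox2-deleted 1 the list median was -0.29, against 0.016 for all genes. The list fell by camera (adjusted p = 0.0225, or 0.589 with an estimated correlation). Hmgb2 had 395 ± 3.61 CPM in control (SD, n = 2) and 202 ± 40.0 CPM in libraries labelled Rbfox2-deleted (SD, n = 3). The securin Pttg1 had 211 ± 23.5 and 92.7 ± 41.3 CPM, Cks1b had 292 ± 45.9 and 142 ± 57.8 CPM, and the kinesin Kif4 had 5.39 ± 2.98 and 0.0681 ± 0.0384 CPM. The G2/M medians were -2.99, 0.05 and -0.78 in Rbfox2-deleted libraries 1, 2 and 3. Some lists that did not pass were also low in Rbfox2-deleted 1, among them Wnt and Notch signalling at -2.95 and DNA damage response at -2.22. Others were not, such as type I interferon response at 0.75. The camera call of G2/M was lost without Rbfox2-deleted 1 (adjusted p = 0.167), without Rbfox2-deleted 3 (adjusted p = 0.0672) and with sex as a covariate (adjusted p = 0.746). It was also lost without control 2 and without controls 1 and 3, fits that leave 1 control sample.

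Stem cell identity genes did not separate the groups as a list. Of 51 HSC identity genes, 25 lay above and 26 below control (median -0.06, camera adjusted p = 0.885), and 1, Pdzk1ip1, was lowered adjusted over the list alone. The quiescence list (adjusted p = 0.903) had the transcription factor Junb at log2 1.06 (SE 0.420), and the multipotent progenitor list (adjusted p = 0.918) had the neutrophil protease Elane at 2.09 ± 1.08 CPM in control (SD, n = 2) and 0.0169 ± 0.0292 CPM in libraries labelled Rbfox2-deleted (SD, n = 3). Alternative splicing regulators, the class Rbfox2 belongs to, did not pass as a list (38 of 62 above control, median 0.22, adjusted p = 0.186), but did without control 2 (adjusted p = 0.0478) and with a GC correction (adjusted p = 0.0425). Rbm25 had 393 ± 0.474 CPM in control (SD, n = 2) and 215 ± 5.30 CPM in libraries labelled Rbfox2-deleted (SD, n = 3), with an edgeR adjusted p = 0.387. The core spliceosome list (adjusted p = 0.413) had Lsm3 at log2 -0.89 (SE 0.293), and the RNA decay list (adjusted p = 0.776) had Rnps1 at 1.35 (SE 0.297).

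In all, 9 of 42 lists passed the camera test, 5 higher and 4 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.54) or with fry (smallest adjusted p = 0.0888). Without Rbfox2-deleted 3, 5 lists passed. The 25 pathway lists that did not pass had adjusted p values from 0.0578 for type I interferon response to 0.918. The interferon list passed as higher under 8 alternatives, among them without control 2 (adjusted p = 0.0220) and without Rbfox2-deleted 2 (adjusted p = 0.0258), and had an adjusted p = 0.521 without Rbfox2-deleted 1 and 0.542 with sex as a covariate. Translation factors (adjusted p = 0.104, but 0.0464 without control 2) had Eif4h at log2 1.69 (SE 0.397), ribosome biogenesis (47 of 76 above control, adjusted p = 0.0749, but 0.0464 as higher without control 2) had Nop10 at -1.23, and type I interferon response had Ifi47 at 1.53 (SE 0.345). G1/S genes (adjusted p = 0.456) had the histone mRNA binding protein Slbp at 1.55 (SE 0.277), p53 targets and apoptosis (adjusted p = 0.834) had the survival gene Bcl2l1 at 2.79 (SE 0.660), and DNA damage response (adjusted p = 0.870) had the Ku70 gene Xrcc6 at 1.66 (SE 0.393). Oxidative stress genes (adjusted p = 0.834) had 1 member raised and 2 lowered adjusted over the list alone, with the transketolase Tkt at 1.80 (SE 0.327). In the mTORC1 list (adjusted p = 0.869) Lamtor5 lay at -0.74 (SE 0.245), in cholesterol and fatty acid synthesis (adjusted p = 0.456) Nsdhl at 2.19 (SE 0.733), and in TGF-beta signalling (adjusted p = 0.822) Tgif1 at 1.12 (SE 0.377). In Wnt and Notch signalling (adjusted p = 0.466) Tcf7l2 lay at -1.67 (SE 0.430), in adhesion and cytoskeleton (adjusted p = 0.207) Arpc5 at 1.58 (SE 0.315), in chromatin regulators (adjusted p = 0.918) Eed at 1.69 (SE 0.458), and in cytokine receptors and JAK-STAT (adjusted p = 0.167) Ptpn11 at -1.37 (SE 0.348). The inflammatory list (adjusted p = 0.834) had Tnf at 0.879 ± 0.168 CPM in control and 0.0172 ± 0.0149 CPM in libraries labelled Rbfox2-deleted. None of these members passed over all genes by edgeR. In 11 lists, 0 of them called, the median, the mean and the camera direction differed in sign. The medians of the 9 called lists kept their sign with DESeq2 factors, library size alone and upper quartile factors, while the median of all genes was 0.11 with TMM, 0.12, 0.22 and -0.20.

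Of 9 summed levels of markers of other cell types, 5 did not overlap between the groups as CPM and 4 with TMM scaling, and 0 of 8 marker lists passed camera. Monocyte, macrophage and dendritic genes summed to 5337 ± 1332 CPM in control (SD, n = 2) and 3230 ± 512 CPM in libraries labelled Rbfox2-deleted (SD, n = 3; exact permutation p = 0.1, the smallest possible), with H2-Aa of antigen presentation at log2 -1.23 (SE 0.455). Erythroid genes summed to 2771 ± 579 and 4844 ± 674 CPM (exact permutation p = 0.1). With TMM scaling the erythroid sum was 2843 ± 436 and 4774 ± 919 CPM. On that scale the carbonic anhydrase Car2 alone had 2574 ± 446 and 4303 ± 680 CPM, so that most of the sum and of its difference came from Car2. Megakaryocyte genes summed to 2202 ± 274 and 3129 ± 261 CPM (exact permutation p = 0.1), and F2rl2 had 4.10 ± 3.62 and 0.0427 ± 0.0145 CPM. B lymphoid and plasma genes summed to 446 ± 104 and 651 ± 61.6 CPM (exact permutation p = 0.1), with Xbp1, which also acts in the unfolded protein response, raised adjusted over the list alone at log2 1.39 (SE 0.300). On the TMM scale the sum was 457 ± 81.1 and 642 ± 108 CPM and Xbp1 alone had 180 ± 15.3 and 470 ± 107 CPM, so that the other genes of the list were lower in sum. With TMM scaling the exact permutation p was 0.2 for the erythroid, megakaryocyte and B lymphoid sums. T and NK genes summed to 536 ± 31.4 and 721 ± 135 CPM (exact permutation p = 0.2, or 0.7 with TMM scaling, where the groups overlapped). The sums of neutrophil (exact permutation p = 0.6), mast and basophil (exact permutation p = 0.5), endothelial (exact permutation p = 0.9) and stromal genes (exact permutation p = 0.6) overlapped between the groups. The leading members of these 5 lists were Ccl5 (0.0152 ± 0.00790 CPM in control and 10.5 ± 9.53 CPM in libraries labelled Rbfox2-deleted), Elane, Cpa3 (5.42 ± 4.72 and 2.74 ± 4.71 CPM), Egfl7 (496 ± 91.2 and 348 ± 92 CPM) and Col1a2 (0.192 ± 0.124 and 1.26 ± 2.05 CPM).

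Mitochondrially encoded genes summed to 55546 ± 430 CPM in control (SD, n = 2) and 43810 ± 7081 CPM in libraries labelled Rbfox2-deleted (SD, n = 3; exact permutation p = 0.2, or 0.1 with TMM scaling), with mt-Co2 at log2 -1.07 (SE 0.302). Immediate early and dissociation stress genes summed to 1332 ± 311 and 1716 ± 621 CPM (exact permutation p = 0.6), with Ppp1r15a at 46.2 ± 1.42 and 119 ± 36.2 CPM. Sex-linked genes summed to 31.5 ± 17.5 and 78.2 ± 41.2 CPM (exact permutation p = 0.3), and the Y-linked gene Uty had 4.05 ± 2.66 and 0.0432 ± 0.0541 CPM.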

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

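The fits with 6 separate libraries, without controls 1 and 3, with sex as a covariate, with a transcript length correction and without identifiers on several rows, and the GC correction and the removal of mitochondrial and hemoglobin genes in the list tests, were chosen after the data were seen. Where a fit left 1 control sample, that sample was assumed to vary like the others, and the cause of a change was not tested. The count of 0 genes by edgeR held under every edgeR and limma-voom setting, with 371 to 2924 genes at an unadjusted p under 0.05 by edgeR and 1686 by limma-voom, and DESeq2 called 477. The 9 lists became 0 with an estimated correlation, 0 with fry and 5 to 12 when each library was left out (5 without Rbfox2-deleted 3). Adjusted p values with an estimated correlation were 0.589 for G2/M and 0.54 for the other 8 lists. With fry they were 0.156 for cytosolic ribosomal proteins and tRNA synthetases, 0.233 for mitochondrial ribosomal proteins and oxidative phosphorylation, 0.0888 for chaperones and MYC, and 0.415 for autophagy, G2/M and glycolysis. Leaving out each library gave 7.23e-07 to 0.244 for mitochondrial ribosomal proteins, 0.0214 to 0.0567 for MYC, 0.00373 to 0.167 for G2/M and 0.000665 to 0.0874 for glycolysis, and the other 5 lists stayed under 0.05. The stricter filter gave MYC 0.189, sex as a covariate gave MYC 0.0801 and G2/M 0.746, and leaving out controls 1 and 3 gave MYC 0.0962 and G2/M 0.0661. The GC correction gave mitochondrial ribosomal proteins 0.492 and oxidative phosphorylation 0.316. Their medians relative to all genes were then -0.39 and -0.55, against -0.56 and -0.68 in the main fit. Camera adjusted p values with the length correction were 0.772 for cytosolic ribosomal proteins, 0.901 for mitochondrial ribosomal proteins and 0.0669 for glycolysis. For oxidative phosphorylation it was 0.725 with the direction reversed. Chaperone, tRNA synthetase and autophagy lists passed under every setting run except the estimated correlation and fry. Lists that did not pass in the main fit passed as higher under some settings: type I interferon without control 2, without Rbfox2-deleted 2, with DESeq2 factors, 6 libraries, the block, and the GC, length and combined corrections (0.0108 to 0.0466), translation factors without control 2, with the block and with the same corrections (0.00916 to 0.0464), ribosome biogenesis without control 2, with the block and with the GC and combined corrections (0.0215 to 0.0464), splicing regulators without control 2 and with the GC and combined corrections (0.0208 to 0.0478), and ubiquitin and ERAD genes with the 3 corrections (0.0298 to 0.0467). Without Rbfox2-deleted 1 the core spliceosome passed as lower (0.0213) and cytokine receptors as higher (0.0347). Marker lists past the threshold numbered 0 to 1 when each library was left out (stromal genes, adjusted p = 0.0156 without control 2) and 1 after the stricter filter (monocyte genes, 0.0130). Rbfox2 had a log2 fold change of 1.90 without controls 1 and 3, where control 2 alone stood for the group, and was negative under the other settings, from -3.76 to -0.13. Named genes far from the threshold changed sign in 6 cases: Egfl7 to 0.074 with the GC correction, Mrps21 to 0.049, Lamtor5 to 0.19 and mt-Co2 to 0.025 with the length correction, Col1a2 to -1.84 with sex as a covariate, and Cpa3 to 0.39 without controls 1 and 3. Of 76 genes, 29 passed the threshold with DESeq2 and none with another tool or setting. Deviations of same-numbered libraries from their group means correlated at -0.046, 0.0024 and 0.070 across genes. Because controls 1 and 3 were nearly identical, these values could not decide whether the replicate numbers pair the samples. With a replicate block on 6 separate libraries edgeR called 0 genes (1348 at an unadjusted p under 0.05) and camera 12 lists, and Rbfox2 was at -3.07. With the block and the GC correction together the counts were 0 genes (743 at an unadjusted p under 0.05) and 11 lists, Rbfox2 was at -2.65, and adjusted p values were 0.786 for mitochondrial ribosomal proteins, 0.730 for oxidative phosphorylation and 0.0520 for glycolysis. At this spread the simulated test recovered 0% of genes changed 2-fold, 2% changed 4-fold, 18% changed 8-fold and 32% changed 16-fold. These genes were picked from those with a mean above 5 CPM.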

Other observations

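The tests of sex, of controls 1 and 3, of exchanged labels and of length-matched genes and the GC correction in the camera test were chosen after the results were seen, and the membrane trafficking and nuclear speckle lists were written after the smallest p values were seen (for speckle genes, those of the fit without Rbfox2-deleted 1) and tested without the genes noticed. The other tests in this part were planned before their results were seen.

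Besides the lists described above, nuclear speckle genes, which include SR-related splicing proteins, lay lower in libraries labelled Rbfox2-deleted. The genes noticed first were Pnn, Srrm2, Prpf4b and Psip1. Of 44 other speckle genes, 33 lay below control, with a median log2 value of -0.46 (camera p = 0.0126, adjusted p = 0.0253 over the 2 lists; adjusted p = 0.311 with an estimated correlation, p = 0.155 unadjusted), and medians of -0.34, -0.85 and -0.30 in libraries 1, 2 and 3. These values do not settle whether speckle transcripts are lower as a group. The list was tested in the same samples in which its first genes were noticed, and the call was lost with an estimated correlation. In addition, 5 of the 44 genes belong to a list fixed earlier. After subtraction of the transcript length trend the mean over the 3 libraries was -0.09 ± 0.98 (SD, n = 3, without the spread between controls). The subtraction also removes each library's overall level, so this mean does not isolate length. The hypothesis that vesicle coat, adaptor and tethering genes are higher, drawn from Arf4 and 5 other genes, was not borne out. Of 90 such genes, 43 lay above and 47 below control, with a median log2 value of -0.05 (camera p = 0.511; p = 0.601 with an estimated correlation), and medians of -0.31, 0.14 and 0.18 in libraries 1, 2 and 3.

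Chaperone genes kept part of their difference against genes of like length and level. Each of 50 chaperone genes was set against 20 genes outside every list matched on transcript length and on mean level over the 5 samples. The median difference was 0.29, 0.24 and 0.19 in libraries 1, 2 and 3 labelled Rbfox2-deleted, or 0.24 ± 0.05 (SD, n = 3), against 0.53 for the list itself. The values of all 3 libraries were taken from the same mean of the control samples. Each SD in this part therefore leaves out the spread between controls. The same comparison gave 0.42 ± 0.25 for tRNA synthetases, 0.40 ± 0.19 for glycolysis and hypoxia genes, 0.28 ± 0.19 for MYC and its targets and 0.22 ± 0.44 for autophagy and lysosome genes, whose difference in Rbfox2-deleted 1 was -0.29. Of the lists that were lower, oxidative phosphorylation kept -0.10 ± 0.09 of -0.56 and mitochondrial ribosomal proteins kept -0.23 ± 0.17 of -0.45. G2/M genes kept -0.62 ± 0.57 of -1.24, with 0.035 in Rbfox2-deleted 2. The list values in this part are means of the list medians over the 3 libraries. They differ from the medians of edgeR log2 fold changes, which for G2/M was -0.21.

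Cytosolic ribosomal protein genes lay at a mean of -0.67 over the 3 libraries labelled Rbfox2-deleted. Sex of the mice is not settled: the list lay at -0.68 relative to the male controls in Rbfox2-deleted 2, but that is the only male library labelled Rbfox2-deleted. Transcript length could account for part of the shift, but the values do not settle it. Genes outside every list of up to 1000 bases lay at -0.72, -0.68 and -0.70. Those of 1000 to 2000 bases, where the list median of 1094 falls, lay at -0.27, -0.13 and -0.13. Lengths were those of each gene's longest annotated transcript, so an expressed form can belong to a shorter bin. After the length trend of all other genes was subtracted, the list mean was 0.013 ± 0.58 (SD, n = 3). That subtraction also removes each library's overall level, so it does not isolate length. In Rbfox2-deleted 1 it moved the ribosomal list to 0.68 and the HSC identity list from -0.10 to 0.98. Libraries 2 and 3 kept -0.26 and -0.38 for the ribosomal list. Length-matched genes of like level left -0.26 ± 0.14. Subtraction of a GC trend left -0.39 ± 0.92 (0.67, -0.82 and -1.03 in libraries 1, 2 and 3), and it too removes each library's overall level. These SDs leave out the spread between the control samples. In the separate fit with a GC correction the list median was -0.14, against 0.46 for all genes (camera adjusted p = 0.0198). These values do not settle whether the rest belongs to ribosomal genes. Of the 10 splits of the 5 samples, 2 gave a result as large (a -log10 p of 16.8 for the real one and 17.3 for Rbfox2-deleted 2 and 3 against the rest), 10 splits are too few for a share under 0.05, and an effect of genotype stays open and untested.

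The splits of the 5 samples also bear on the counts of genes and lists. The real split gave 1221 genes at an unadjusted p under 0.05, where the highest other gave 896, and 9 lists, where the highest other gave 7. In both counts 1 of 10 splits, the real one, gave a result as large, and 10 splits are too few for a share under 0.05.

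Rbfox2 reads did not follow the labels, with 0.213 CPM in control 2 and 2.44 CPM in Rbfox2-deleted 2. By distance between whole libraries, control 2 lay with controls 1 and 3. Its chi-square per degree of freedom was 3.10 times larger to the nearest library labelled Rbfox2-deleted than to the farther of controls 1 and 3. Rank correlation and genes lost in one library gave the same order. But controls 1 and 3 count as 1 sample, and depth also followed the labels. These distances therefore do not settle whether control 2 came from a deleted mouse. Whether Rbfox2-deleted 2 came from a control mouse is not settled: the nearest control was 2.74 times as far as Rbfox2-deleted 3 in chi-square but nearer than Rbfox2-deleted 1 (ratio 0.742), and it was also nearer than Rbfox2-deleted 3 in rank correlation (0.901 against 0.900) and in genes lost in one library (382 against 427). Loss of rare transcripts in single libraries of about 500 cells could account for control 2, since 8.49% of 1826 genes of like level in controls 1 and 3 had as low a ratio of control 2 to those libraries. Reads from exons outside the deletion in Rbfox2-deleted 2, or incomplete deletion, stay open, because gene counts do not show exons.

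Controls 1 and 3 were nearly identical. High depth of libraries from different mice is argued against, since control 2, at a depth between theirs, differed from them by 254 and 281 genes with at least 100 counts in one library and at most 1 in the other, while controls 1 and 3 differed by 0 such genes. One pool of cDNA or a library read more than once could give this, with a chi-square per degree of freedom of 3.44 against 156 for the closest other pair. The excess over Poisson noise grew with abundance, from 1.72 for genes with a mean of 20 to 100 counts to 15.1 above 10000 counts. No biological explanation was tested.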
